A study of Mus musculus with 7 samples.

How the data were processed

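RNA was immunoprecipitated with an antibody to EZH2, the histone methyltransferase of Polycomb repressive complex 2, from mouse embryonic stem cells (RIP-seq). The cells were a male CAST/B6 line with a recombinase cassette at Rosa26, kept with 15% serum at 37 °C and 5% CO2 and given doxycycline for 3 days; the labels do not say what the doxycycline induced. The 7 libraries fell into 3 groups: wild type (WT, n = 3, the parental line and clones 20 and 44), Ezh2 knockout (EZH2 KO, n = 2, clones 12 and 19), and double knockout of Safb and Safb2 (SAFB DKO, n = 2, clones 13 and 4). Replicates were therefore separate clones or the parental line. The p-values of features and genes measured the spread between these, pooled over the 3 groups, and those of shares used only the groups compared. The EZH2 KO libraries differed most from each other. SAFB DKO against WT thus also carried their spread, and comparisons with EZH2 KO may understate it. Camera, a list test, compared genes of a list with other genes. Sign tests and bootstrap intervals ran over genes and carried no spread between clones. Both SAFB DKO labels carried the same replicate number, so they were numbered in the order of the labels. Libraries were made with a ribosomal RNA depletion kit from 9 µL of precipitated RNA and 1 µL of ERCC spike-in; counts of the spike-in were not analysed here, and precipitates with a control antibody were not used here.

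The deposited table held counts, whole numbers of reads per feature, without normalization. Per the file headers, the authors counted reads with featureCounts 2.0.3 in reverse-stranded mode on intervals in mm10; the aligner and the peak caller were not given in the sources used here. The 303889 features lay on 1 strand each, and their names stated that they were called on the pooled WT libraries. Pooled columns of the same table equalled the sums of their single libraries in all 303889 features (tolerance 0) and were used only for this check. Another 3 value columns, named after a control antibody, belonged to none of the 7 samples and were not used here. Besides the table, the authors deposited a filtered list of 33671 peaks and a short list of 10043 peaks, given as intervals. Every short-list peak was in the filtered list. Short-list peaks had at least 93 reads in the pooled WT libraries, and the highest such count among the remaining filtered peaks was 92, so the lists were chosen on these WT libraries and are not independent evidence of a fall from WT.

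Total counts were 21832539, 21051227 and 19024702 in WT, 7050832 and 8353603 in EZH2 KO, and 18738499 and 15812517 in SAFB DKO. The columns of the EZH2 KO libraries were named by another pattern, and 1 sequencing sample number was carried both by an EZH2 KO and by a WT library, so the names point to another sequencing run for EZH2 KO than for WT and SAFB DKO; the labels did not state the runs. If so, genotype and run coincide in each comparison with EZH2 KO, and no fit had run as a term. Shares of counts in single libraries were given 95% exact Clopper-Pearson intervals. Where a group had no count of a feature, 3 counts over the group served as the floor for a bound on the fold. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

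Features were annotated with GENCODE M21 (basic) on their strand as coding exon, untranslated region, noncoding exon, intron, antisense to a gene or intergenic. Of all features, 223722 overlapped 1 gene, 7446 overlapped more and 72721 none. Gene-level counts were sums over the features of 1 gene; features of 2 or more genes were left out. Because the features were called on WT precipitates, gene-level values describe precipitated RNA in those intervals, not expression.

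Comparisons used edgeR 4.0.16 (quasi-likelihood F-test, filterByExpr) in R 4.3.3, with the 7 libraries in 1 fit by group, which left 192964 features and 16710 genes. Library sizes were column totals scaled by TMM factors from the 170869 tested features outside the filtered list, called reference features here, since the listed peaks were expected to move as a class. Benjamini-Hochberg adjusted p under 0.05 counted as a change, with "rose" and "fell" kept for such results. Levels are normalised counts scaled to library size (CPM, edgeR cpm) with SD, fold changes are on the log2 scale with SE; n is 3 for WT and 2 for each knockout. The comparison of SAFB DKO with EZH2 KO is also the test of the difference between the knockout effects.

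Lists of 15 gene groups were tested with camera (limma 3.58.1, voom values, preset correlation 0.01), adjusted over lists and comparisons. The same test with an estimated correlation called no list in any comparison, so its p stands beside each call; fry, a test of whether members changed at all, was a further alternative. Genes in near-identical copies, such as ribosomal protein genes, histones and 7SK, can share reads with their copies or pseudogenes. Shares of counts were compared by exact two-sided permutation tests, whose smallest p is 0.1 for 3 libraries against 2 and 0.333 for 2 against 2, so they cannot pass 0.05. No comparison had 3 libraries in both groups, so regrouping the libraries was not informative.

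The named features and genes followed a rule: for each comparison, the 10 features (at most 1 per gene) and 5 genes with the largest fall, and as many with the largest rise, among those past the threshold, above the median abundance and without overlap between the libraries of the groups compared; the 10 short-list peaks most abundant in WT; the 4 most abundant members of each list; and Safb, Safb2, Ezh2, Xist, Tsix, Kcnq1ot1, Airn, Malat1 and Neat1. Outside the rule, Gpi1, Ldha and Pfkp were named in the closing section after their values were seen, and Snhg11 and Lars2 only for their annotation. Groups, lists, comparisons, tests and this rule were fixed before the data were examined. Alternatives were other scalings (TMM over all features, column totals, DESeq2 1.42.0 size factors), DESeq2's Wald test, other count filters, fits on the compared groups alone, on the listed peaks alone, against a fold of 1.5 (glmTreat), with a replicate block, and with each library left out; the closing section gives their effect. Thinning to the smallest library, shares without the 2 biggest short-list peaks, column totals and DESeq2 size factors at gene level, tests of features without counts at their bound, and runs of a list of low-oxygen genes were chosen after seeing the data. A ranking of the lists by score could not be run, since they hold no score. A planned comparison of purine content with fold change was void: sequence of the feature was at hand for 26.8% of exonic tested features and 2.39% of the short list, under the 80% set as the minimum. Overlaps used GenomicRanges (1.54.1) in place of the planned bedtools, with rtracklayer (1.62.0) and data.table (1.17.8), and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

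The feature and gene fits were tested on simulated data with these depths and dispersions, with changes placed in short-list peaks and in genes of more than 50 counts per library. Of features changed 4-fold, 61% were recovered for SAFB DKO against WT, 54% for EZH2 KO against WT and 50.5% for SAFB DKO against EZH2 KO, and of those changed 2-fold 10%, 6% and 4.5%. At gene level 98% or more of 4-fold and 66% to 72% of 2-fold changes were recovered. False calls numbered 2 to 9 among unchanged features and 11 to 18 among unchanged genes. Spread was equal in all simulated groups, while in the data the EZH2 KO libraries differed most from each other. These numbers therefore do not show how many false calls arise under unequal spread. Only 200 features or genes were changed in each simulated knockout, while 37932 and 30058 features were called in SAFB DKO and EZH2 KO against WT. The adjusted threshold was thereby stricter than in the data, so the recovered shares are not the sensitivity of the reported fits. A list shifted 2-fold in simulated SAFB DKO was called in both comparisons with that group (adjusted p = 3.1e-04 by camera with an estimated correlation). None of the 14 other lists was called by any of the 3 list tests. Genes were simulated independently of each other, so this does not show false calls or power of the list tests among correlated genes.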

Results

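RNA precipitated with an EZH2 antibody was counted in mouse embryonic stem cells of 3 genotypes. By the title of the series, the antibody was made against the human protein and also recognises SAFB, a nuclear RNA-binding protein. Loss of Safb and its paralog Safb2 (SAFB DKO, n = 2 clones) against wild type (WT, n = 3) asks which precipitated RNA depends on SAFB proteins. Loss of Ezh2 (EZH2 KO, n = 2 clones) against WT asks which depends on EZH2. SAFB DKO against EZH2 KO compares the knockouts without the libraries on which the peaks were called. Total counts ran from 19024702 to 21832539 in WT, from 15812517 to 18738499 in SAFB DKO and from 7050832 to 8353603 in EZH2 KO. By their column names EZH2 KO libraries seem to come from another sequencing run, in which case each difference from EZH2 KO is one of genotype and run together. Intervals and floors below cover counting error only.

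The targeted genes had lost their counts in the matching genotype. Safb (17:56584825-56606294) had 200 ± 71.9 CPM in WT, 299 ± 21.2 in EZH2 KO and 1.00 ± 0.581 in SAFB DKO (mean ± SD, log2 fold change in SAFB DKO -7.59, SE 0.41, adjusted p = 9.5e-08, -8.39 without SAFB DKO replicate 1). Safb2 (17:56560965-56584585) had 239 ± 99.2, 682 ± 94.1 and 1.86 ± 1.49 CPM (-6.95, SE 0.49, adjusted p = 2.8e-07, -8.21 without SAFB DKO replicate 1). Ezh2 (6:47530139-47595341) had 180 ± 19.2 CPM in WT, 157 ± 19.5 in SAFB DKO and 1.21 ± 1.48 in EZH2 KO (-7.19, SE 0.37, adjusted p = 2.4e-07, -10.10 without EZH2 KO replicate 1 and -6.31 without replicate 2). Correlations of log2 counts were 0.923 to 0.930 between WT libraries, 0.891 between the SAFB DKO libraries and 0.736 between the EZH2 KO libraries.

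**Figure D1:**
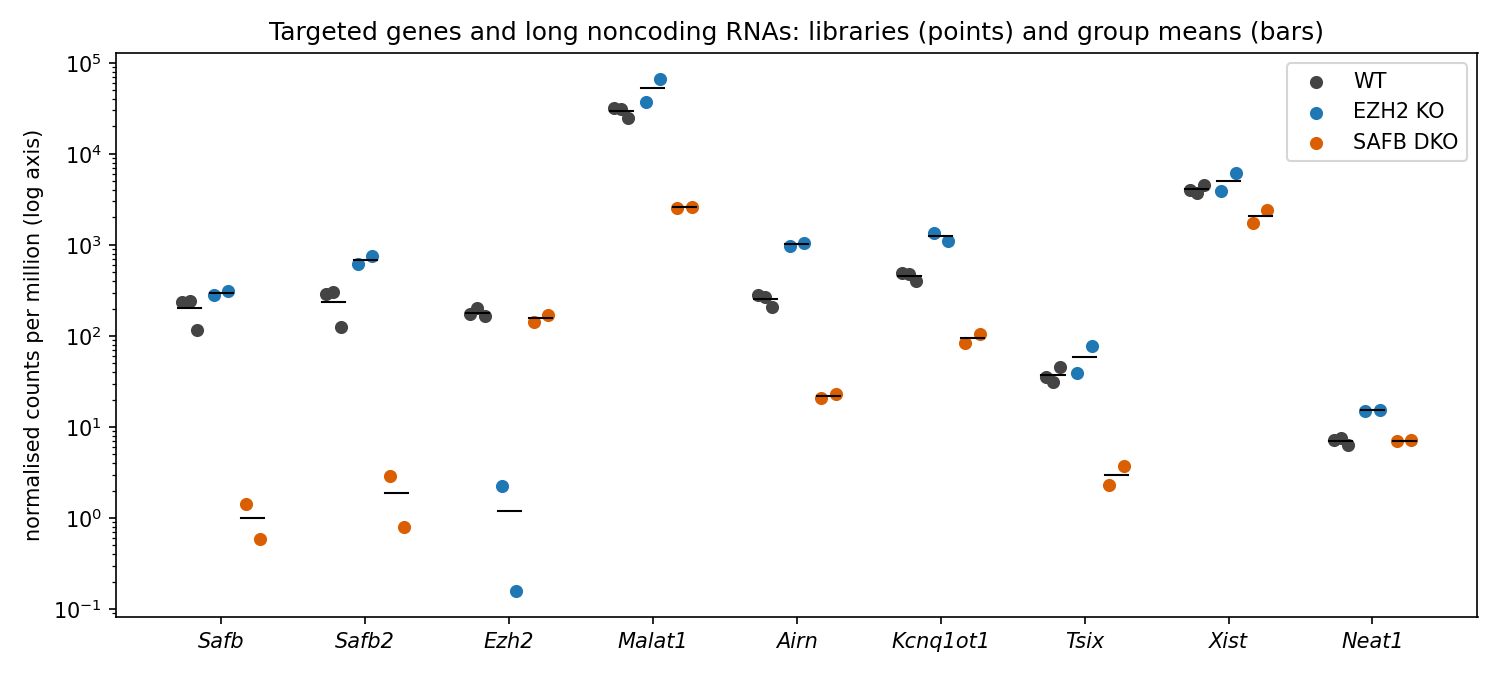
Normalised counts of the targeted genes and of long noncoding RNAs in each library (points), with group means (bars). Libraries of 7050832 to 21832539 counts are shown on a log axis.

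The 10043 short-list peaks held 15.8% (95% exact interval 15.7349 to 15.7654), 15.7% (15.6587 to 15.6898) and 15.0% (14.9713 to 15.0033) of counts in the WT libraries. They held 1.84% (1.83677 to 1.84895) and 2.12% (2.11395 to 2.12815) in SAFB DKO, and 24.1% (24.0988 to 24.162) and 27.3% (27.3155 to 27.376) in EZH2 KO. The mean share was thus 7.81 times higher in WT than in SAFB DKO and 1.66 times higher in EZH2 KO than in WT. Each comparison with WT had an exact permutation p = 0.1, the smallest that 10 splits allow, and SAFB DKO against EZH2 KO had an exact permutation p = 0.333, the smallest for 6 splits. Malat1 alone, an abundant nuclear RNA, took 2.94 ± 0.404% of counts in WT, 4.32 ± 1.10% in EZH2 KO and 0.303 ± 0.00570% in SAFB DKO. The small nuclear RNA 7SK (Rn7sk) went the other way, with 1.73 ± 0.170%, 0.127 ± 0.00971% and 3.11 ± 0.0366%, and mitochondrial features took 0.364 ± 0.0930%, 0.0670 ± 0.0293% and 0.781 ± 0.0955%.

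**Figure D2:**
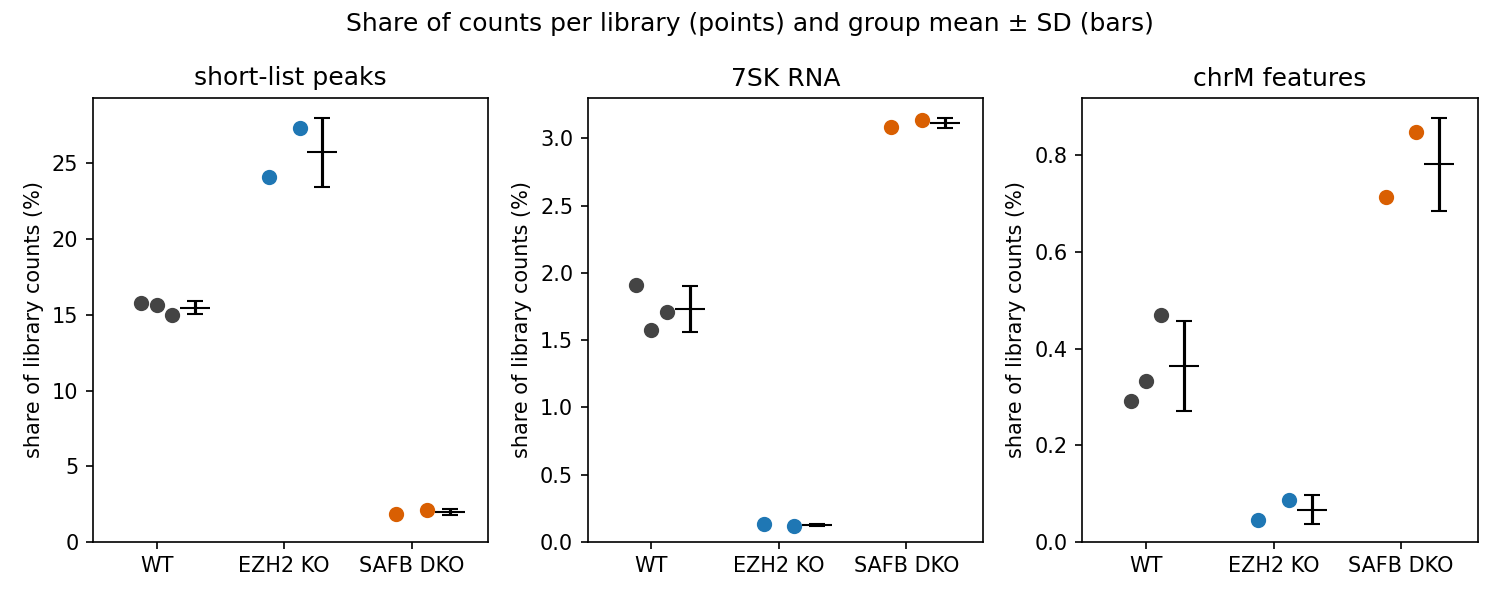
Share of counts in the short-list peaks and in other RNA classes, by library. Short-list peaks held 15.0% to 15.8% in WT, 24.1% to 27.3% in EZH2 KO and 1.84% to 2.12% in SAFB DKO.

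In SAFB DKO against WT, short-list peaks fell almost as a class. The largest peak, in Malat1 (19:5800677-5802530), fell from 29049 ± 4078 to 2277 ± 38.0 CPM (-3.67, SE 0.19, adjusted p = 4.1e-09). An intronic peak of Etl4 (2:20537705-20542067) fell from 689 ± 7.21 to 63.8 ± 4.12 CPM (-3.43, SE 0.15, adjusted p = 2.9e-09). A coding peak of Rtn4 (11:29706508-29708778), which encodes an endoplasmic reticulum protein, fell from 712 ± 37.5 to 141 ± 3.73 (-2.34), and an intronic peak of Cnot1 (8:95786055-95788906) fell from 390 ± 12.4 to 74.9 ± 6.53 (-2.38). An intronic peak of the calcium channel gene Cacnb2 (2:14692326-14694488) had 7.96 ± 0.726 CPM in WT and no counts in SAFB DKO, at least 107-fold lower. An intronic peak of the glutamate receptor gene Gria4 (9:4744363-4746144) was at least 73.4-fold lower. Of the 10043 short-list peaks 9735 (96.9%) fell and 0 rose by edgeR's quasi-likelihood test, with a median of -3.24 (9.44-fold), also with the 306 peaks lacking SAFB DKO counts at their bound. No short-list peak rose at an unadjusted p under 0.05 or by DESeq2, and with any 1 library left out 8690 to 9974 fell. Because the short list was chosen on WT counts, this comparison favours falls, and the effect of the unstated criterion of the filtered list is unknown. Reference features, on which the scaling was set, had a median of -0.02, with 18026 falls and 4354 rises. Their classes differed. Intergenic ones had a median of -1.56 (3579 of 11646 fell, 63 rose) and antisense ones -0.59 (2327 of 11181 fell, 123 rose). Those in coding exons had 0.36 (1749 of 43623 fell, 1714 rose). Falls were thus not confined to the listed peaks.

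Over all tested features 33578 fell and 4354 rose in SAFB DKO against WT. This total of 37932 was 24115 without WT replicate 1, 24913 without WT replicate 2, 23637 without SAFB DKO replicate 1 and 19583 with a mean of at least 50 counts. The last of these totals came from fewer tested features, since only those past that filter were fitted. Falls made up 88.5% of the 37932 calls, but 83.6%, 73.8% and 72.9% with TMM over all features, column totals and DESeq2 size factors. These scalings moved the median of all features by 0.09, 0.22 and 0.25. Among short-list peaks 5570 (55.5%) were intronic, 2559 (25.5%) intergenic, 1378 (13.7%) antisense to a gene and 265 (2.64%) in noncoding exons, and the share that fell was 98.2%, 95.1%, 95.6% and 97.4%. The 162 peaks in coding exons had a median of -2.54, and the intronic ones -3.33. Over all tested features the median was 0.61 lower on the log2 scale in introns than in exons (-0.30 and 0.31).

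**Figure D3:**
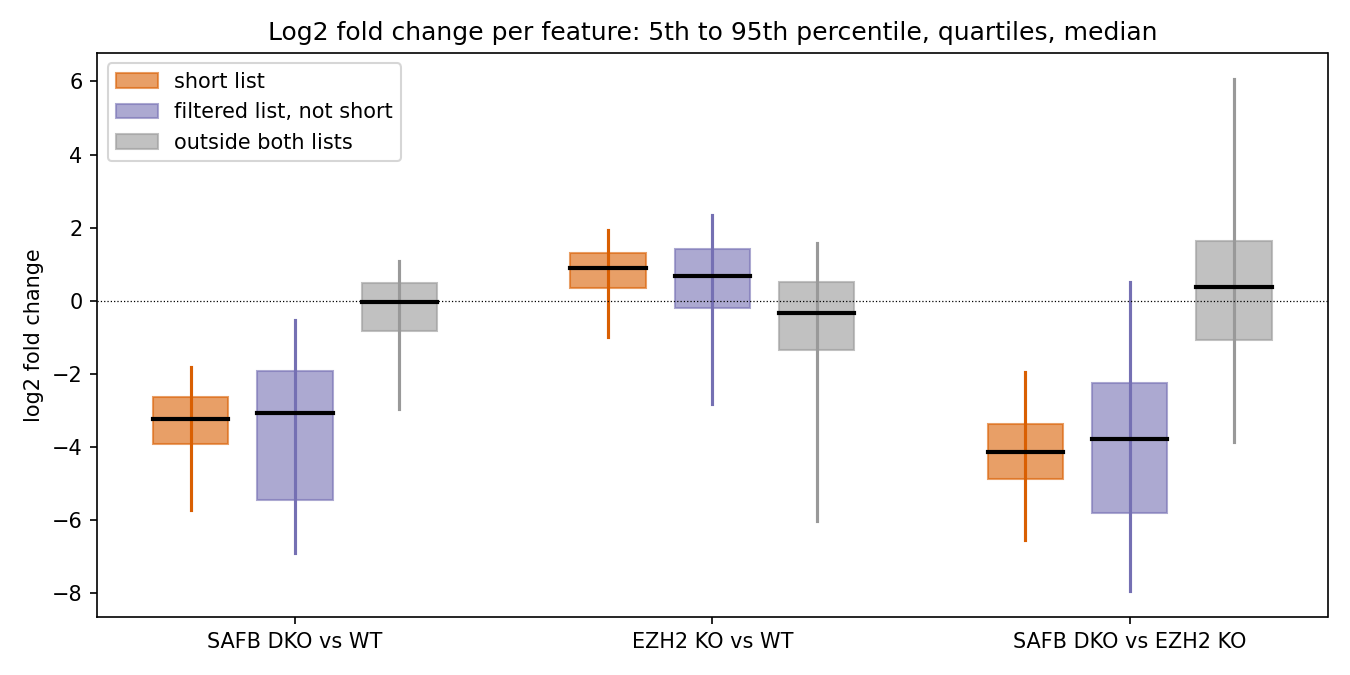
Log2 fold changes of short-list peaks, of the other filtered peaks and of reference features in each comparison. Peaks without counts in a group are drawn at their fitted value. Short-list medians were -3.24 in SAFB DKO against WT, 0.89 in EZH2 KO against WT and -4.15 in SAFB DKO against EZH2 KO.

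Several long noncoding RNAs with known roles in imprinting and X inactivation fell in SAFB DKO, by different amounts. Airn, which silences Igf2r in cis, fell from 253 ± 38.4 to 21.8 ± 1.71 CPM (-3.53, SE 0.17, adjusted p = 9.5e-08), Kcnq1ot1 from 456 ± 47.3 to 94.7 ± 15.7 (-2.27, SE 0.16, adjusted p = 2.8e-07) and Tsix, the antisense partner of Xist, from 37.2 ± 7.13 to 3.00 ± 1.01 (-3.64, SE 0.33, adjusted p = 1.5e-06). Xist fell less, from 4093 ± 455 to 2091 ± 478 CPM (-0.97, SE 0.19, adjusted p = 8.8e-04), and Neat1, the scaffold of paraspeckles, had 7.02 ± 0.643 and 7.10 ± 0.234 (0.01, adjusted p = 0.961). Of 22 tested genes of the list of chromatin and imprinted long noncoding RNAs, which also holds Peg3 and Snhg11, annotated as protein-coding, 15 fell and 1 rose (17 and 1 adjusted over the list alone, median -0.68, camera adjusted p = 4.5e-04, adjusted p = 0.351 with an estimated correlation).

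In EZH2 KO against WT Airn, Kcnq1ot1, Malat1 and Neat1 (1.12, adjusted p = 0.00124) rose. Airn rose from 253 ± 38.4 to 1018 ± 56.8 CPM (2.01, SE 0.14, adjusted p = 2.9e-06) and Kcnq1ot1 from 456 ± 47.3 to 1239 ± 174 (1.44, SE 0.14, adjusted p = 1.5e-05). Malat1 rose from 29280 ± 4093 to 52261 ± 20829 (0.84, SE 0.19, adjusted p = 0.003), though by 0.36 without EZH2 KO replicate 2, and the Etl4 peak rose from 689 ± 7.21 to 1891 ± 462 (1.46, adjusted p = 9.4e-06). Tsix had 37.2 ± 7.13 and 58.9 ± 27.5 CPM (0.66, adjusted p = 0.0493, but 0.08 without EZH2 KO replicate 2 and uncalled also without WT replicate 1 or 2, with TMM over all features and with column totals). Xist had 4093 ± 455 and 5012 ± 1516 (0.29, adjusted p = 0.201, but 0.57 and called without EZH2 KO replicate 1). Of the 22 genes of the same list 5 fell and 8 rose, Peg3 among the latter (0.34, adjusted p = 0.0499), (5 and 8 adjusted over the list alone, median 0.23, camera adjusted p = 0.50, adjusted p = 0.764 with an estimated correlation). Among genes, Hormad2, a meiotic gene, rose from 54.8 ± 3.12 to 553 ± 138 CPM (3.34, SE 0.24, adjusted p = 3.2e-06), Meis2 rose by 2.40 (adjusted p = 1.0e-05) and Olig2, a neural transcription factor, rose from 11.4 ± 1.63 to 48.1 ± 10.9 (2.08, SE 0.21, adjusted p = 1.7e-05).

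Short-list peaks had a median of 0.89 (1.86-fold) in EZH2 KO against WT, from 0.65 to 1.08 with 1 library left out; 4290 rose and 149 fell. The rises were 2641, 2688 and 2672 without WT replicate 1, 2 and 3, and the falls 36, 48 and 38, or 588 without EZH2 KO replicate 2, 258 with column totals and 85 with a replicate block, and against a fold of 1.5 they were 2414 and 65. Over all features 15579 fell and 14479 rose. This total of 30058 was 13803, 14359 and 12511 without WT replicate 1, 2 and 3, 50052 without EZH2 KO replicate 2, 14466 against a fold of 1.5 and 15597 with a replicate block. Falls made up 51.8% of calls, and 62.5%, 71.1% and 51.5% with TMM over all features, column totals and DESeq2 size factors, which moved the median of all features by -0.13, -0.25 and 0.01. At gene level 3765 fell and 4227 rose in EZH2 KO, but 4565 and 3532 with TMM over all features, 5383 and 3112 with column totals and 3840 and 4432 with DESeq2 size factors, so the majority depended on scaling. In SAFB DKO 5783 genes fell and 2551 rose, or 5501 and 3327, 5112 and 4538, and 4876 and 4587 with these scalings.

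Several abundant RNAs fell in EZH2 KO and rose in SAFB DKO, while others did not. 7SK (Rn7sk, 9:78175303-78175633), an inhibitor of transcription elongation, fell in EZH2 KO from 17228 ± 1806 to 1493 ± 112 CPM (-3.53, SE 0.14, adjusted p = 2.0e-08) and rose in SAFB DKO (0.62, SE 0.12, adjusted p = 6.8e-04). The ribosomal protein genes Rpl8 and Rplp0 had 427 ± 17.1 and 207 ± 11.4 CPM in WT, fell in EZH2 KO (-1.41 and -1.62) and rose in SAFB DKO (0.94 and 0.75), while Rps15a went the other way (0.63, or 0.39 without EZH2 KO replicate 2, and -1.18). Pcbp2, an RNA-binding protein gene, fell by 2.05 in EZH2 KO and rose by 0.75 in SAFB DKO, and the extracellular matrix gene Fn1 fell by 1.07 and rose by 0.82. The splicing factor genes Hnrnpl and Srrm2 did the reverse (0.75 and 0.53 in EZH2 KO, -0.69 and -0.97 in SAFB DKO). Gm26917, the most abundant of these in WT, rose in SAFB DKO (0.75, adjusted p = 4.8e-05). In EZH2 KO it had 0.26 (adjusted p = 0.0494), uncalled without any 1 of the WT or SAFB DKO libraries and with TMM over all features or column totals. Hsp90aa1 fell in EZH2 KO (-0.98) and had -0.06 in SAFB DKO (adjusted p = 0.677).

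Of 65 ribosomal protein genes 3 fell and 40 rose in SAFB DKO (3 and 44 adjusted over the list alone, median 0.58, camera adjusted p = 9.7e-12, adjusted p = 0.260 with an estimated correlation). In EZH2 KO 40 fell and 1 rose (43 and 1 alone, median -0.70, 6.8e-09, adjusted p = 0.351 with an estimated correlation). Of 27 replication-dependent histone genes 0 fell and 16 rose in SAFB DKO by edgeR (0 and 18 adjusted over the list alone, median 0.68, camera adjusted p = 6.8e-09, adjusted p = 0.199 with an estimated correlation). In EZH2 KO 24 fell and 0 rose (24 and 0 alone, median -1.14, 3.2e-08, adjusted p = 0.199 with an estimated correlation). Of 26 hnRNP genes 2 fell and 15 rose in SAFB DKO (2 and 16 adjusted over the list alone, median 0.40, camera adjusted p = 1.7e-04, adjusted p = 0.635 with an estimated correlation). In EZH2 KO 18 fell and 2 rose (20 and 2 alone, median -0.78, 7.7e-07, adjusted p = 0.593 with an estimated correlation). Of 6 mitochondrial genes 0 fell and 4 rose in SAFB DKO (0 and 5 adjusted over the list alone, median 0.74, camera adjusted p = 0.00388, adjusted p = 0.635 with an estimated correlation). In EZH2 KO 6 fell (6 alone, median -2.02, 3.4e-05, adjusted p = 0.580 with an estimated correlation).

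Of 9 tested genes of a list of contaminating RNAs, 7SK and the protein-coding Lars2 among them, 1 fell and 7 rose in SAFB DKO (1 and 7 adjusted over the list alone, median 0.72, camera adjusted p = 1.7e-04, adjusted p = 0.404 with an estimated correlation). In EZH2 KO 4 fell and 2 rose (5 and 3 alone, median -0.74, 0.289, 0.0157 by fry, adjusted p = 0.675 with an estimated correlation). Of 31 genes of SR splicing factors 17 fell and 5 rose in EZH2 KO (17 and 6 adjusted over the list alone, median -0.53, camera adjusted p = 0.00635, but 0.0542 without EZH2 KO replicate 1, 0.0669 with the top feature of a gene and 0.0772 by fry, adjusted p = 0.675 with an estimated correlation). In SAFB DKO 7 fell and 6 rose (7 and 6 alone, median 0.18, mean -0.05, 0.234, adjusted p = 0.792 with an estimated correlation). By fry the hnRNP and mitochondrial lists were not called in SAFB DKO (0.0911 and 0.133). No called list changed direction with any of the 3 other scalings.

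The Polycomb lists were not called by camera in either knockout, but fry, which asks whether members changed rather than whether they changed more than other genes, called some. Of 14 genes of PRC2 subunits and partners, Suz12 had log2 fold changes of 0.24 in SAFB DKO and 0.15 in EZH2 KO, neither past the threshold. Without EZH2 KO replicate 1 both were called (0.24 and 0.44), and without replicate 2 the former was. Mtf2 fell by 0.58 (adjusted p = 0.00546) and rose by 0.79 (adjusted p = 6.9e-04). In SAFB DKO 3 of the 14 fell and 5 rose (3 and 5 adjusted over the list alone, median 0.23, camera adjusted p = 0.163, adjusted p = 0.675 with an estimated correlation). In EZH2 KO 4 fell and 4 rose (4 and 4 alone, median -0.03, mean -0.61 with the deleted Ezh2 included, 0.539, adjusted p = 0.834 with an estimated correlation). Of 26 PRC1 genes 9 fell and 4 rose in SAFB DKO (9 and 4 adjusted over the list alone, median -0.15, though camera ranked the list upward, camera adjusted p = 0.865, 0.0467 downward by fry, adjusted p = 0.912 with an estimated correlation). In EZH2 KO 8 fell and 7 rose (8 and 7 alone, median 0.12, 0.891, adjusted p = 0.926 with an estimated correlation). Of 49 Polycomb target genes 16 were tested. In SAFB DKO 7 fell and 0 rose by edgeR (7 and 0 adjusted over the list alone, median -1.19, camera adjusted p = 0.369, 0.00125 downward by fry, adjusted p = 0.638 with an estimated correlation). In EZH2 KO 2 fell and 7 rose, among these Olig2 and Otx2 (1.14, adjusted p = 1.1e-04), with 2 and 7 alone (median 0.12, mean -0.54, upward by camera, 0.486, 0.00405 upward by fry, adjusted p = 0.675 with an estimated correlation).

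Of 39 pluripotency genes, Tet1 fell by 0.64 in SAFB DKO (adjusted p = 4.6e-04) and rose by 0.60 in EZH2 KO (adjusted p = 7.6e-04). In SAFB DKO 10 of the 39 fell and 15 rose (10 and 15 adjusted over the list alone, median 0.20, camera adjusted p = 0.0898, but 0.0435 without SAFB DKO replicate 1, 0.0175 with column totals and 0.0154 with DESeq2 size factors, upward each time, adjusted p = 0.675 with an estimated correlation). In EZH2 KO 14 fell and 10 rose (15 and 10 alone, median -0.19, 0.356, adjusted p = 0.764 with an estimated correlation). Of 25 genes of the SAFB family and nuclear matrix RNA-binding proteins 10 fell and 6 rose in SAFB DKO, the deleted Safb and Safb2 among the falls (10 and 6 adjusted over the list alone, median 0.04, mean -0.79, downward by camera, camera adjusted p = 0.586, 0.0238 by fry, adjusted p = 0.833 with an estimated correlation). In EZH2 KO 12 fell and 7 rose (13 and 8 alone, median -0.34, 0.234, adjusted p = 0.675 with an estimated correlation). Lists for other cell types were not called by camera. Of 17 feeder fibroblast markers 6 fell and 2 rose in SAFB DKO (6 and 2 alone, median -0.76, 0.522, 0.0360 by fry, adjusted p = 0.764 with an estimated correlation). In EZH2 KO 7 fell and 2 rose (8 and 2 alone, median -0.81, 0.0992, but 0.0125 without EZH2 KO replicate 1 and 0.0458 by fry, adjusted p = 0.635 with an estimated correlation). Of 15 differentiated lineage markers 5 fell and 1 rose in SAFB DKO (5 and 1 alone, median -0.43, 0.335, 0.00239 by fry, adjusted p = 0.635 with an estimated correlation), and 4 fell and 1 rose in EZH2 KO (4 and 1 alone, median -0.22, 0.355, adjusted p = 0.635 with an estimated correlation). Of 16 interferon and stress genes 4 fell and 4 rose in SAFB DKO (4 and 4 alone, median 0.10, mean -0.12, 0.380, adjusted p = 0.675 with an estimated correlation), and 5 fell and 0 rose in EZH2 KO by edgeR (4 and 0 alone, median -0.34, 0.0992, but 0.0451 without WT replicate 2, 0.0467 with column totals and 0.0421 by fry, adjusted p = 0.635 with an estimated correlation).

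Compared directly, SAFB DKO was lower than EZH2 KO at nearly the whole short list. Airn (-5.54, SE 0.19, adjusted p = 2.6e-09), Kcnq1ot1 (-3.71, SE 0.18, adjusted p = 7.6e-09), Malat1 (-4.34, SE 0.24, adjusted p = 1.2e-08) and Meis2 (43.1 ± 10.4 in EZH2 KO and 0.406 ± 0.187 CPM in SAFB DKO, -6.74, SE 0.36, adjusted p = 9.2e-09) fell. Outside both peak lists, an intronic reference feature of the GABA receptor gene Gabrg3 (7:57270451-57272419) without SAFB DKO counts was at least 243-fold lower. Rpl8 rose by 2.35 and 7SK (Rn7sk) by 4.15. Of 10043 short-list peaks 9532 fell and 2 rose (median -4.15, 17.8-fold, -4.14 with peaks without counts at their bound), and 9087 to 9609 fell with any 1 library left out. Reference features had a median of 0.37. Falls made up 58.3% of all 77059 calls, and 51.1%, 43.5% and 50.5% with TMM over all features, column totals and DESeq2 size factors, which moved the median by 0.22, 0.47 and 0.24. The total was 46086 (29290 fell) with only the compared groups fitted. It was 30092 with a mean of at least 50 counts, where fewer features were tested. At gene level 6886 fell and 4806 rose, or 6286 and 5555, 5664 and 6485, and 6253 and 5659 with these scalings, so column totals turned the majority.

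Between the knockouts camera called 7 lists. Ribosomal protein genes (4 fell, 47 rose, 4 and 48 adjusted over the list alone, median 1.30, camera adjusted p = 1.0e-11, adjusted p = 0.260 with an estimated correlation), histones (0 fell by edgeR, 26 rose, 0 and 26 alone, median 1.91, 1.9e-09, adjusted p = 0.199 with an estimated correlation), hnRNP genes (3 and 22, 3 and 22 alone, median 1.15, 3.8e-07, adjusted p = 0.593 with an estimated correlation) and mitochondrial genes (0 and 6, 0 and 6 alone, median 2.76, 1.3e-04, adjusted p = 0.593 with an estimated correlation) were higher in SAFB DKO. So were the contaminating RNAs (1 and 8, 1 and 8 alone, median 1.46, 0.00388, adjusted p = 0.580 with an estimated correlation) and SR genes (6 and 16, 6 and 16 alone, median 0.45, 0.0181, but 0.0510 without EZH2 KO replicate 1, 0.421 with the top feature and 0.133 by fry, adjusted p = 0.675 with an estimated correlation). The list of long noncoding RNAs was lower (14 and 4, 14 and 5 alone, median -0.91, 0.0394, but 0.0538 without SAFB DKO replicate 1 and uncalled with each other scaling or the top feature, adjusted p = 0.593 with an estimated correlation). Not called were PRC1 (12 and 9, 14 and 9 alone, median -0.42, 0.978, 0.984 estimated), PRC2 (3 and 6, 3 and 6 alone, median 0.43, 0.163, 0.675), Polycomb targets (7 and 2, 7 and 2 alone, median -0.998, 0.401, 0.663) and the SAFB family (9 and 12, 9 and 12 alone, median 0.53, mean -0.66, 0.447, 0.791). Nor were differentiated lineage (6 and 2, 6 and 2 alone, median -0.37, 0.793, 0.833), feeder (3 and 5, 3 and 3 alone, median 0.14, mean -0.32, 0.356, 0.675), interferon (4 and 7, 4 and 7 alone, median 0.21, 0.173, 0.638) and pluripotency genes (13 and 20, 15 and 20 alone, median 0.41, 0.176, 0.675). Fry called PRC1 (0.0206), Polycomb target (7.3e-04) and differentiated lineage genes (0.0157) downward and interferon genes (0.0478) upward, and camera with column totals called pluripotency genes upward (0.0437).

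Calls against WT overlapped mainly with opposite signs. Of features, 10432 fell in SAFB DKO and rose in EZH2 KO, where independent calls would give 2520, and 1969 rose and fell, against 352. Each of these differed also between the knockouts directly, which opposite calls within the same fit make nearly certain. Airn, Kcnq1ot1, Malat1 and the Etl4 peak were of the former kind, 7SK and Rpl8 of the latter. On the short list 4239 fell and rose, against 4158 by chance, and at gene level 2997 and 1636, against 1463 and 575. In the same direction 505 features fell and 46 rose, against 2711 and 327. This total of 551 was 98, 140 and 102 without WT replicate 1, 2 and 3, 3110 without EZH2 KO replicate 2, 349 without SAFB DKO replicate 1, 862 with column totals, 1062 with only the compared groups fitted and 176 against a fold of 1.5. The log2 fold changes correlated at -0.286. Unchanged groups simulated against the same WT libraries, with equal spread in all groups, gave 0.295 on average and 0 features called in both.

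**Figure D4:**
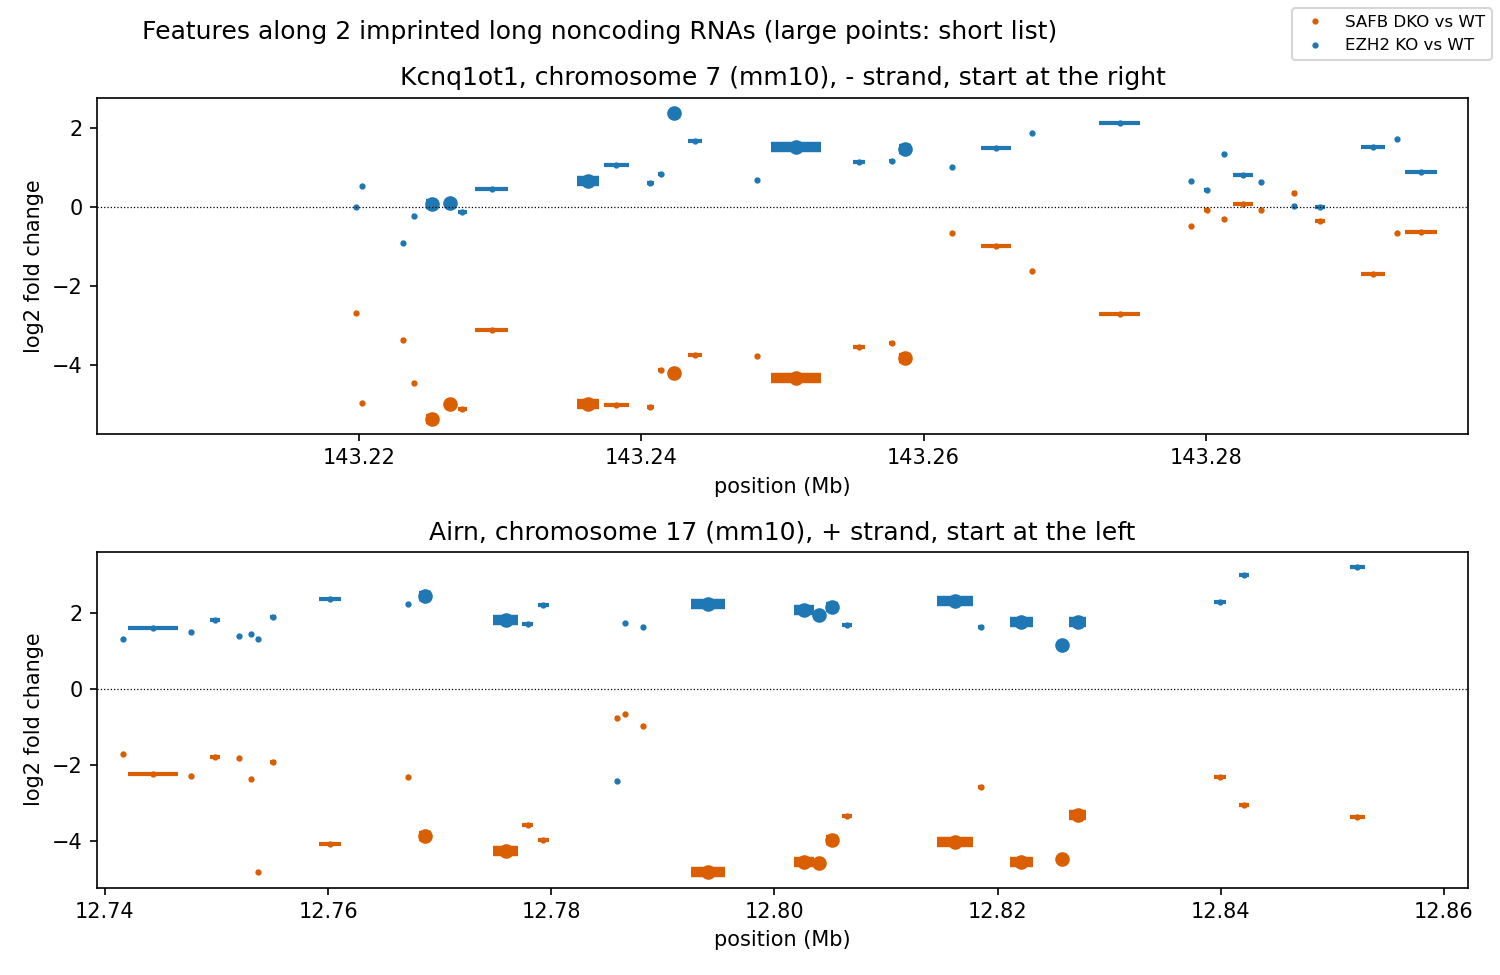
Log2 fold changes of features along Kcnq1ot1 and Airn in the knockouts against WT; features without counts in a group are drawn at their bound. Kcnq1ot1 starts at 7:143296549 and Airn at 17:12741311.

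Along Kcnq1ot1 the fall in SAFB DKO was uneven. The 18 features nearer to its start had a median of -0.67 (9 fell), and the 15 farther away a median of -4.96, or -4.47 with 1 feature at its bound (15 fell). Along Airn the medians were -2.31 nearer (14 of 18 fell) and -3.69 farther (12 of 12), and -3.69 with features at their bound. Among the filtered-list features of Airn alone (14) the fall did not grow with distance (rank correlation 0.253, or 0.314 at the bound), while those of Kcnq1ot1 (7) had -0.929, or -0.179 with 1 at its bound and -0.886 without it. Both RNAs are transcribed over long distances in antisense direction to an imprinted gene. These parts were compared only after the position effect had been seen, without a test.

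Among genes that rose in SAFB DKO, Upp1, a uridine phosphorylase gene, rose from 33.3 ± 6.46 to 121 ± 33.6 CPM (1.87, SE 0.19, adjusted p = 5.1e-06) and Smtnl2 from 23.8 ± 2.55 to 76.2 ± 7.66 (1.68, SE 0.15, adjusted p = 1.4e-06). Pnma5 rose from 5.68 ± 0.545 to 23.3 ± 11.8 (2.04, but 1.39 without SAFB DKO replicate 1), Bnip3, a gene of mitophagy, from 10.3 ± 7.23 to 37.0 ± 11.9 (1.84, adjusted p = 0.0017, or 2.58 without WT replicate 2) and Gm2a from 13.2 ± 2.08 to 42.2 ± 17.6 (1.68, adjusted p = 6.0e-05, or 1.16 without SAFB DKO replicate 1). The largest gene-level falls after the targeted genes included Cfap299, from 19.9 ± 1.34 to 0.619 ± 0.0373 CPM (-4.99, SE 0.33, adjusted p = 2.1e-07), and Wls, a carrier of Wnt proteins, from 35.0 ± 5.78 to 1.35 ± 0.681 (-4.72, or -5.35 without SAFB DKO replicate 2). In EZH2 KO Trh, a hormone precursor gene, fell from 38.5 ± 8.38 to 4.95 ± 1.68 CPM (-2.96, SE 0.26, adjusted p = 8.8e-06), with a log2 fold change of -0.17 in SAFB DKO (adjusted p = 0.492).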

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

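Of the tests here, those on the choice of peaks in WT, on scaling, on library size, on independent molecules and on the sequencing run were chosen only after the result was seen. Comparing the knockouts directly, 4239 short-list peaks and 2997 genes fell in SAFB DKO, rose in EZH2 KO and differed between them. Another 1636 genes did the reverse. Opposite calls within the same fit make that direct difference nearly certain, so it adds little. The long noncoding RNAs Airn (-5.54), Kcnq1ot1 (-3.71), Malat1 (-4.34) and Tsix (-4.30, from peaks around its annotated end alone) fell in SAFB DKO against EZH2 KO.

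Short-list peaks fell in SAFB DKO. A choice of peaks for high WT counts alone would lower any library that took no part in it. In EZH2 KO their median against WT was 0.89 (0.65 to 1.08 with 1 library left out). EZH2 KO is not a neutral reference, however, since its share of abundant RNAs and, by column names, its run differed too. These could hide such a lowering. The other filtered peaks, with fewer WT reads, had a median of -3.06 in SAFB DKO against WT, or -2.68 with those without counts at their bound. Of these 12052 tested peaks 5817 fell and 0 rose by edgeR. The fall was thus not limited to peaks chosen for the highest WT counts. The unstated criterion of the filtered list was not tested, so a choice of peaks stays open. Scaling moves all features alike, yet short-list peaks lay -3.21 from the reference features (-3.35 to -3.10 with 1 library left out). Lower abundance of the whole host transcript would lower its exons too. Over 1859 host genes, however, intronic peaks lay -3.28 from exonic features outside the lists (95% bootstrap interval over genes -3.33 to -3.25). Loss of SAFB proteins from the precipitate is a candidate explanation that stays open. So do other effects of the genotype, such as lower levels of these RNAs themselves, since total RNA was not analysed here. An equal loss of all intronic RNA is argued against by a median of -0.17 in reference introns and -3.33 in short-list introns. A wider but unequal loss of intronic and intergenic RNA stays open. Reference introns lay below reference coding exons (0.36), and reference intergenic features had a median of -1.56. The unstated criterion that split the intron sets also limits this comparison.

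EZH2 KO libraries had many empty features and differed more from each other at low counts. At equal totals 10.3% to 11.5% of features were at 0 in WT libraries, 27.9% and 29.0% in SAFB DKO, and 32.2% and 46.1% in EZH2 KO. Against WT, a smaller library size alone is thus argued against. The features were called on WT, however, which favours few empty features there. SAFB DKO libraries were nearly as empty as EZH2 KO replicate 2, so many empty features were not particular to EZH2 KO. Fewer independent molecules per library may account for the empty features and the scatter in EZH2 KO. Chi-square per degree of freedom between the EZH2 KO libraries was 4.04 at sums of 5 to 10 thinned counts, against 2.08 between the SAFB DKO and at most 1.41 between WT libraries. Its excess over 1 changed 1.24 times toward sums of 20 to 40, where it was 4.75. At those sums it was 2.44 between the SAFB DKO and 1.47 to 1.59 between the WT libraries. The excess thus stayed near level in these groups too, and only its size set EZH2 KO apart. Genotype and another sequencing run, to which the column names point, cannot be told apart, because 1 sequencing sample number was carried by both a WT and an EZH2 KO library and no other genotype shared the naming of EZH2 KO.

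Many abundant RNAs, such as 7SK and most called ribosomal protein and histone genes, were low in EZH2 KO and high in SAFB DKO, though Hnrnpl, Srrm2 and Rps15a went the other way and Gm26917 did not fall in EZH2 KO. Fewer independent molecules in EZH2 KO would not shift the share of an abundant RNA, but the lowest WT share of 7SK was 11.8 times the highest EZH2 KO share, with at least 9404 counts in each library. Over 9672 genes without a filtered-list peak, exonic fold changes of the knockouts against WT had a Spearman correlation of -0.421 (95% interval -0.440 to -0.402). The shared WT libraries push this value up. Genes that ranked high in SAFB DKO thus tended to rank low in EZH2 KO. A different share of background RNA in the precipitates stays open, but this correlation cannot decide on it. A share that scaled all background RNA alike would shift these genes together, and a rank correlation does not see a common shift. Whether genotype, run or handling set the opposite changes stays open too.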

How the results depend on the processing

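With 2 or 3 libraries per group, counts of calls depended on single libraries of each group, EZH2 KO was by its column names confounded with the run, and a lone library left in a group was assumed to vary like the others. Of 318 alternative values of main results 267 kept their verdict, 39 were weaker, 7 stronger, 5 moved and 0 reversed. Of 6828 values of named results 6412 stayed, 245 were weaker, 159 stronger and 12 reversed. For the changes below the cause was not tested. The tolerance for intronic against exonic peaks was set to the replicate SD after seeing the data, as were thinning and the removal of the 2 biggest peaks. With features without counts at their bound, also chosen later, the background correlation was -0.396 and opposite peaks differed by 0.639 (5th percentile 0.917). A ranking by score had no score column, and purine content within bins was void.

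Column totals gave 258 short-list falls in EZH2 KO, 862 features called alike in both knockouts, and Hspa5 at 0.26 between the knockouts. A mean of at least 50 counts gave 19583 calls in SAFB DKO and 30092 between the knockouts. Short-list falls were then 5649, 50 and 5637 in SAFB DKO, EZH2 KO and between them. Fewer features and short-list peaks were tested there, so these counts cannot be set directly against the main ones. Fits on the compared groups gave 46086 calls between the knockouts and 1062 called alike. Fits on short-list peaks gave 9934, 4659 and 9632 calls and 188 alike; on filtered peaks 18211, 5187, 17975 and 247. Against a fold of 1.5 EZH2 KO had 14466 calls, 65 short-list falls and 2414 rises, with 176 alike; with a replicate block 15597 calls and 85 falls.

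Camera with an estimated correlation called 0 lists in SAFB DKO, 0 in EZH2 KO and 0 between them (2 each at an unadjusted p under 0.05), and fry 8 in EZH2 KO and the PRC1 list in SAFB DKO downward (0.0467). The difference in short-list share between the knockouts was -20.6 points without the top 1% of features; without the 2 biggest peaks it was -20.5, and -11.1 in SAFB DKO against WT. Introns minus exons were 0.60 in EZH2 KO and -1.23 between the knockouts within count bins. The top feature of a gene alone reversed Jarid2 (-0.47 in SAFB DKO, -0.95 between the knockouts), Cbx7 (0.41, -0.45 in EZH2 KO, 0.86 between them), Tfap2c (-0.28 in SAFB DKO), Sparc (-0.54 in EZH2 KO) and Rbm25 (-0.093 between the knockouts).

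With 1 library left out, calls ranged from 23637 to 56309 in SAFB DKO, 12511 to 50052 in EZH2 KO and 60786 to 88850 between them. Short-list falls in EZH2 KO ranged from 36 to 588 and rises from 2641 to 5071, and features called alike from 98 to 3110. The highest number of calls in SAFB DKO against WT came without EZH2 KO replicate 1, a library outside that comparison that shared its estimate of spread. An intronic Mid1 peak in EZH2 KO ranged from -0.84 (without EZH2 KO replicate 2) to 1.32, and a feature at 3:62159411-62159493 in SAFB DKO from -1.65 (without SAFB DKO replicate 1) to 3.59.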

Other observations

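Chosen after a result was seen were the tests of features without counts at their bound or left out, the matching of random peaks on count, and the tests of the low-oxygen list without single libraries and over exonic features. Genes known to be induced by low oxygen were among the rises in SAFB DKO. Of 43 tested members of a list of 45 such genes 24 rose and 5 fell (median 0.64, and -0.23 for all genes), or 14 and 3 without SAFB DKO replicate 1, with the glycolytic genes Gpi1 (380 ± 102 to 998 ± 251 CPM, 1.39, adjusted p = 9.8e-05), Ldha (1.15, adjusted p = 5.8e-05) and Pfkp (1.42, adjusted p = 6.8e-06) among the rises, while in EZH2 KO 22 fell and 3 rose. Exonic features shifted the same way in general: over these alone the list had a median of 0.84 and all genes 0.19, and WT replicate 2 lay 0.28 above the WT mean of the list. Camera gave p = 4.9e-09 with the preset correlation and p = 0.190 with an estimated one, and fry p = 0.0256, or p = 0.120 without SAFB DKO replicate 1. The bound set beforehand, p of 0.05 or more with an estimated correlation as evidence against a wider rise, was met but set aside after that p was seen, because this test called 0 of 15 other lists, even histones with 0 falls and 16 rises by edgeR, so the question stays open.

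Peaks far from the start of Kcnq1ot1 fell more in SAFB DKO than near ones. Over 553 other genes with at least 5 filtered-list features, the median within-gene Spearman correlation of distance and log2 fold change was -0.0857 (sign test p = 0.00396). This value rested on fitted fold changes of features without counts: it was 0.0182 with these at their bound (exact sign test p = 0.548) and 0.0180 over 448 genes without them (exact sign test p = 0.599). Along Kcnq1ot1 itself it was -0.929 over 7 features and -0.886 over the 6 with counts in both groups, but -0.179 with the other 1 at its bound, and distance also went with the count of a feature (-0.893), while along Airn it was 0.253, 0.301 and 0.314. A trend with distance therefore stays open.

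Some short-list peaks lay opposite to a far stronger peak, with a median of 2.00% of its counts. In 93 such pairs (0.926% of the short list) fold changes of the weak and the strong peak differed by a median of 0.621. This was below the 5th percentile of 0.951 for random short-list peaks matched to the count of the weak peak. The strong peaks had at least 20 times the counts of the weak ones, so their fold changes carried less counting error than those of the random peaks. The random peaks were matched on count only after a first run without matching, which gave the same verdict. A smaller difference could arise from the higher counts alone, so the test cannot decide whether reads assigned to the opposite strand form part of these weak peaks. A shared change of neighbouring peaks stays open too.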
